A study of Homo sapiens with 6 samples.

How the data were processed

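The series measured RNA by sequencing in T24 and UMUC3 cells, established human bladder cancer lines, after knockdown of circPTK2, a circular RNA from the PTK2 locus. The 6 libraries comprise 1 control and 2 knockdown libraries per line. Per the labels, the sample titles name siRNAs with the numbers 1 and 2, whereas the series' design text names sh constructs, so the kind of knockdown reagent is not settled by the sources used here. In T24 the siRNA number in the title and the number in the name of the matching data column are swapped, and in UMUC3 they match. Replicate numbers are those of the titles. Nothing in the labels says that the 2 knockdown libraries of a line came from separate cultures, so p-values measure only the spread between these samples, which may be technical, and any difference between the siRNAs adds to that spread.

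The authors deposited a table of raw read counts per transcript, with 136953 transcripts and no normalisation. Per the submitters' processing notes, FastQC 0.11.5, HISAT2 2.1.0, StringTie 1.3.3b and the hg38 build were used, and those notes give no role or order for these tools. Whether the libraries kept strand, and whether poly(A) RNA was selected, is not given in the sources used here. Reads from overlapping or antisense genes and from near-identical copies can therefore not be told apart. Of the transcripts, 121915 carry a gene and 15038 carry neither a gene nor a position. The latter held 14.86 to 16.1% of the counts of a library and were left out of library sizes and tests. The other transcripts were summed to 30717 genes. Transcript identifiers matched GENCODE release 29 for 121869 of them, and 121252 had identical coordinates there, so gene coordinates below are from that annotation on GRCh38. Counts per transcript were assigned by the authors, and a transfer of reads between similar transcripts alters a gene's sum where those transcripts belong to different genes or to no gene. Linear transcripts and the circular RNA of PTK2 share exons, so no value is given for circPTK2 and its knockdown was not checked.

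Total counts per library were 65111683 to 72362436, of which 55071837 to 60780176 fell in named genes. The chi-square statistic of the paired knockdown libraries per degree of freedom was 115.9 in T24 and 112.4 in UMUC3, so neither pair agreed within sampling noise and all 6 libraries were counted separately.

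Genes with at least 10 counts in at least 2 libraries and at least 30 counts in total were tested (20721 genes). Fold changes, standard errors and p-values are from edgeR 4.0.16 (TMM normalisation, robust quasi-likelihood fit, quasi-likelihood F test) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. Both lines together were fitted with line and knockdown as terms (3 residual degrees of freedom). Each line, and the difference between the lines, was fitted with 4 groups (2 residual degrees of freedom), in which the lone control library is assumed to vary like the paired knockdown libraries. Levels are given as CPM, counts scaled to library size with TMM factors. Gene lists were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01 between genes, with the correlation estimated per list, and with fry. Lists with under 5 measured members were not tested.

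The design, the filter, 31 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The rule names the genes of the axis in the series' title (PTK2, PABPC1, SETDB1), the 10 highest and 10 lowest fold changes in both lines together, 8 and 8 in each line, and 6 and 6 in the difference. These genes had to pass the threshold, to have a mean of at least 5 CPM and, for the knockdown comparisons, to lie on 1 side of the control in every knockdown library. From each list it takes up to 2 members that passed in each direction. Where fewer than 5 genes passed, the 5 with the smallest p are considered. A few genes that meet this rule are not reported here. The lists cover mesenchymal, epithelial, luminal and basal urothelial markers, matrix proteases, integrins, TGF-beta, YAP, WNT and p53 genes, gemcitabine metabolism, H3K9 methylation, poly(A) binding and mRNA decay, DNA replication, mitosis, apoptosis, interferon, inflammatory, immediate early, unfolded protein, hypoxia, cholesterol, oxidative phosphorylation, ribosomal, NRF2 and microRNA machinery genes. Further lists hold mitochondrially encoded genes and replication-dependent histones, as signs of RNA quality and selection, and immune and stromal markers, as signs of other cell types.

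A second gene set was added after seeing the data. Many genes had reads that moved between their transcripts from library to library. For each gene with at least 2 transcripts, the composition shift is the largest share of its counts that changed transcript between any pair of libraries of a line. The 4593 tested genes with a shift under 0.2 in both lines are called composition-stable, and the tests were repeated on them alone with unaltered library sizes and factors. The shift compares transcripts of the same gene only. A composition-stable gene may therefore still gain or lose reads to other genes or to transcripts with no gene. Pairs of control and knockdown libraries and of the paired knockdown libraries both count, so the set also leaves out genes whose change or spread is carried by 1 transcript. This selection lowers the dispersion and may make p-values in the set too small. Common dispersion in the fit of both lines together was 0.202 over all genes and 0.0552 over composition-stable genes. Tests of gene lists on the difference between the lines were also added after seeing the data.

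The gene tests were checked on simulated counts drawn with the means, library sizes and dispersions of the real genes, with 200 genes changed. At a log2 fold of 2, 64% of 100 changed genes were recovered for both lines together over all 20721 genes, and none of 100 in T24, UMUC3 or the difference. Among 4593 composition-stable genes the recovery was 99% for both lines together, 94% in T24, 92% in UMUC3 and 64% in the difference. At a log2 fold of 1 it was 79%, 40%, 38% and 13%. Among the calls of that set, 7.2%, 13.5%, 9% and 11.4% were unchanged genes, which is above the nominal 5%. Counts were simulated for genes already chosen as composition-stable, and that choice was not repeated on the simulated counts. These shares therefore leave out false calls that the choice itself may add. Over all genes 16 unchanged genes, 19% of the calls, were called for both lines together, the single call in T24 and the single call in the difference were unchanged genes, and UMUC3 had 0 calls. A list shift of 0.5 on the log2 scale passed camera in every simulated comparison and no comparison with an estimated correlation, which had adjusted p values of 0.132 to 0.833. Fry missed the planted list in 5 of 8 comparisons. Of the lists without a planted shift, camera called 1 and fry 2 in T24 over all genes, and camera 1 and fry 2 in both lines together among composition-stable genes. Simulated genes were drawn independently of each other, so these runs cannot show whether the preset correlation of 0.01 holds for the real lists. In both lines together over all genes, the estimated correlation was 0.84 for mitochondrially encoded genes and 0.451 for DNA replication genes. The planted folds were alike in both lines, and the simulated dispersions were those of the per-line fit. Differences between the lines, which add spread to the real fit of both lines together, were therefore not simulated. Common dispersion in that real fit was 0.202 over all genes and 0.0552 among composition-stable genes, against 0.168 and 0.0391 in the per-line fit. The recovery of 64% and 99% for both lines together thus does not carry over to the real data.

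Alternatives were DESeq2 1.42.0, limma voom, RLE size factors, library sizes alone, no count filter, a filter of 50 counts, the legacy and the non-robust quasi-likelihood fit, a test against a 1.5-fold change, the siRNA number as a block, other samples in the fit, and leaving out each library (control libraries only for both lines together). For the last observations, 7-base sequences in annotated 3' UTRs were related to fold changes in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1, and this search was checked on simulated sequences, where a planted shift of -0.2 ranked 1 from the lowest.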

Results

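RNA was sequenced from T24 and UMUC3 cells, human lines derived from bladder carcinoma, with and without knockdown of circPTK2, to ask how gene expression changed when this circular RNA was reduced. Each line contributed 1 control library and 2 knockdown libraries. Total counts were 68886057 in the T24 control, 72137247 and 72362436 in the T24 knockdown libraries, 65111683 in the UMUC3 control, and 66227109 and 71355753 in the UMUC3 knockdown libraries. The lines differed far more than the conditions. The median absolute log2 difference between the T24 and UMUC3 controls was 0.98, against 0.39 and 0.41 between the T24 control and its knockdown libraries, 0.47 and 0.46 in UMUC3, and 0.26 and 0.28 between the paired knockdown libraries of T24 and UMUC3.

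The series' title links circPTK2 with PABPC1, a poly(A)-binding protein, and SETDB1, a histone H3K9 methyltransferase. Counts of PTK2 (ENSG00000169398, GRCh38 chromosome 8, 140657900 to 141002216, minus strand) measure its linear transcripts and possibly reads from the circle, so they do not check the knockdown. PTK2, which encodes focal adhesion kinase, stood at 45.9 CPM in the T24 control and 67.2 and 63.1 CPM in the knockdown libraries, and at 123.8 CPM in the UMUC3 control and 161.3 and 393.5 CPM in the knockdown libraries. Its log2 fold change in both lines together was 0.83 ± 0.39 (SE; 4 knockdown against 2 control libraries; edgeR adjusted p = 0.497). It was not separated from 0 in T24 (0.51 ± 0.59, adjusted p = 0.777) or UMUC3 (1.16 ± 0.60, adjusted p = 0.44). SETDB1 (ENSG00000143379, chromosome 1, 150926263 to 150964744, plus strand) was measured at 25.6 CPM in the T24 control against 33.4 and 19.9 CPM after knockdown, and at 18.5 CPM in the UMUC3 control against 15.9 and 21.5 CPM. The knockdown libraries of each line lay on both sides of the control, and the log2 fold change in both lines together was 0.04 ± 0.27 (edgeR adjusted p = 0.971). PABPC1 (ENSG00000070756, chromosome 8, 100685816 to 100722809, minus strand) was at 695.5 CPM in the T24 control and 763.3 and 794.0 CPM after knockdown, and at 1979 CPM in the UMUC3 control and 1512 and 1668 CPM after knockdown. Neither the T24 value (log2 0.16 ± 0.09, edgeR adjusted p = 0.517) nor the UMUC3 value (-0.32 ± 0.08, adjusted p = 0.198) passed the threshold. The composition shift, the share of a gene's counts that changed transcript between libraries of a line, reached 0.70 for PTK2 in UMUC3, 0.75 for SETDB1 in T24 and 0.54 for PABPC1 in T24.

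In both lines together, knockdown libraries had less CDK4 mRNA and more COL4A1 mRNA than the control of their own line. CDK4 (ENSG00000135446, chromosome 12, 57747727 to 57756013), a cyclin-dependent kinase of the G1 phase, fell by 2.44 ± 0.12 on the log2 scale (edgeR adjusted p = 0.0168). It went from 142.4 CPM to 28.8 ± 0.6 CPM (mean ± SD, n = 2) in T24 and from 302.7 CPM to 50.8 ± 0.8 CPM (n = 2) in UMUC3. COL4A1 (ENSG00000187498, chromosome 13, 110148963 to 110307233), a chain of basement membrane collagen, rose by 1.85 ± 0.10 (adjusted p = 0.0184), from 341.2 to 1212 ± 85 CPM in T24 and from 7.17 to 26.1 ± 1.0 CPM in UMUC3. CACYBP (-2.76 ± 0.21) and LMNB1 (-1.47 ± 0.12), next by p, had an edgeR adjusted p of 0.0664 each, and 0.50 or more of their counts changed transcript within a line. Over all 20721 genes the test thus called 1 gene higher and 2 lower, with 2400 genes at an unadjusted p under 0.05, while voom called 2 and DESeq2 981. With the siRNA number as a replicate block, from titles or column names, edgeR called 0 genes here (1901 and 1780 at an unadjusted p under 0.05) and in each comparison over all genes below. CDK4 then stood at -2.44 and COL4A1 at 1.84, with adjusted p values of 0.275 and 0.141 each.

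Among the 4593 composition-stable genes, chosen after seeing the data, 14 genes rose and 33 fell in both lines together, and in all 47 every knockdown library lay on the same side of its control. The genes that fell most were CDK4 (adjusted p = 0.00356 in this set), WSB2 (-2.35 ± 0.20), a substrate adaptor of ubiquitin ligases, and NAA50 (-2.17 ± 0.21), an N-terminal acetyltransferase. HIGD1A (-2.14), SURF2 (-2.08), FAM167A (-1.80), TAF9B (-1.70), CHD6 (-1.66), RRM2B (-1.57) and RASSF3 (-1.46) followed, with edgeR adjusted p values from 0.0128 to 0.037. RRM2B encodes the p53-inducible subunit of ribonucleotide reductase and belongs to the gemcitabine metabolism list. The genes that rose most were SGCB (2.09 ± 0.28), a sarcoglycan, COL4A1 (adjusted p = 0.00384), SEMA3A (1.43 ± 0.12), a secreted guidance factor, and SRCAP (1.23 ± 0.13), a chromatin remodeller. F3 (1.18 ± 0.10), which encodes tissue factor, KLF13 (1.10), ID3 (1.10), MIDN (1.00), IGF2R (0.91) and LRFN4 (0.89) were also higher, with adjusted p values between 0.0247 and 0.0415. In the fits that left out a knockdown library 0 genes passed edgeR over all genes, where CDK4 stood at -2.47 to -2.42 with adjusted p values of 0.139 to 0.195. Among composition-stable genes 2 to 4 passed in these fits, CDK4 and COL4A1 in each of the 4. Leaving out the T24 control, so that the effect rests on UMUC3, gave 134 calls over all genes and 570 among composition-stable genes, and leaving out the UMUC3 control gave 25 and 192.

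**Figure D1:**
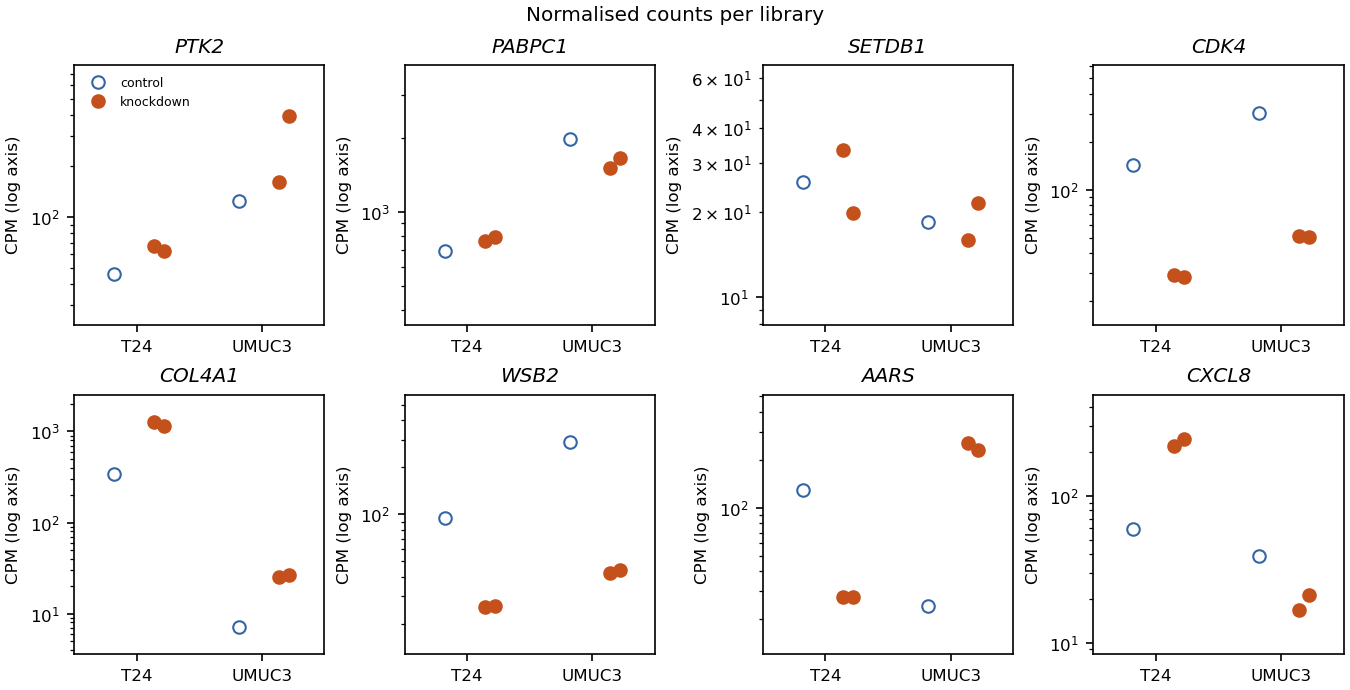
Normalised counts (CPM, log axis) of 8 genes in each of the 6 libraries, with open circles for the control and filled circles for the paired knockdown libraries of T24 and UMUC3. CDK4 and WSB2 lie lower and COL4A1 higher after knockdown in both lines, whereas AARS falls from 129.9 CPM in T24 and rises from 24.2 CPM in UMUC3.

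Of the lists fixed in advance, 11 passed camera in both lines together over all genes, and none kept an adjusted p under 0.05 with an estimated correlation or with fry. Mesenchymal markers were shifted upward (median log2 0.44, 17 of 29 members positive, camera adjusted p = 0.000178, adjusted p = 0.419 with an estimated correlation). Over all genes 0 members passed edgeR, and adjusted over the list alone 11 passed upward and 0 downward. Its members with the smallest p, the fibrillin gene FBN1 (1.32 ± 0.13) and the collagen gene COL5A1 (2.33 ± 0.22), had an adjusted p of 0.068 each. Cholesterol synthesis genes were shifted downward (median -0.34, 20 of 24 negative, camera adjusted p = 0.000178, adjusted p = 0.452 with an estimated correlation), and 2 members passed downward adjusted over the list alone. IDI1 stood at -0.89 ± 0.18, not past the threshold over all genes. Ribosomal protein genes were shifted downward by a small amount (median -0.12, 33 of 40 negative, camera adjusted p = 0.00166, 0.611 with an estimated correlation), with no member called; RPL7 stood at -0.30 and RPLP1 at -0.21. Matrix proteases and inhibitors (median 0.31, camera adjusted p = 0.0204), TGF-beta response genes (0.43, adjusted p = 0.0117), and immediate early genes (0.31, adjusted p = 0.0101) were shifted upward. So were integrins (0.14, adjusted p = 0.0212), hypoxia and glycolysis genes (0.11, adjusted p = 0.0256) and unfolded protein and ATF4 response genes (0.12, adjusted p = 0.0204). These 6 lists had adjusted p values of 0.419 to 0.73 with an estimated correlation. Among composition-stable genes TGF-beta (camera adjusted p = 0.458), immediate early (0.0638) and hypoxia genes (0.191) did not pass. Adjusted over the list alone, 6 protease genes passed upward and 1 downward, 4 TGF-beta genes upward and 1 downward, and 3 immediate early genes upward and 1 downward. Values that did not pass were 1.37 for the protease gene ADAM19, and 0.42 and 0.41 for the chaperone genes HSP90B1 and PDIA4. Among composition-stable genes, the immediate early regulator ETV5 fell (-1.03 ± 0.10, edgeR adjusted p = 0.0337), and the TGF-beta target ID3 and the ferritin gene FTH1 of the NRF2 list rose (FTH1 0.64 ± 0.07, adjusted p = 0.0348). Mitochondrially encoded genes (10 of 10 positive, median 0.19, camera adjusted p = 0.0101, 0.692 with an estimated correlation), listed as a sign of RNA quality, moved upward with these groups. So did replication-dependent histones (25 of 31 positive, median 0.48, camera adjusted p = 0.0101, 0.419 with an estimated correlation), listed as a sign of RNA selection. What moved either list was not tested. Histone examples were HIST1H2AC (1.57 ± 0.33) and HIST1H2BC (1.81 ± 0.42), neither past the threshold.

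The remaining lists did not pass camera in both lines together. Camera adjusted p values were 0.217 for H3K9 methylation, 0.222 for immune markers, 0.238 for stromal and endothelial markers, mitosis, DNA replication and oxidative phosphorylation, 0.328 for p53 targets, 0.381 for WNT and 0.448 for interferon. They were 0.607 for gemcitabine metabolism, 0.619 for YAP targets, 0.766 for poly(A) binding and mRNA decay, 0.794 for microRNA machinery, epithelial markers and apoptosis, 0.842 for NRF2 and basal markers, 0.883 for luminal markers and 0.895 for inflammatory genes. Immune markers had 7 and stromal markers 11 measured members, and no member of either passed edgeR.

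In T24, JUN, LTBP2 and TGFBR2 were among the genes with more mRNA in the knockdown libraries, and CDK4 and AARS among those with less. Over all genes edgeR called 19 genes higher and 9 lower (2598 at an unadjusted p under 0.05; DESeq2 980, voom 0). JUN, an AP-1 transcription factor with a single transcript in the table (ENSG00000177606, chromosome 1, 58780788 to 58784327), rose from 7.9 CPM to 272.1 and 265.0 CPM (log2 5.09 ± 0.09, adjusted p = 0.00695). LTBP2, which encodes an extracellular matrix protein, rose from 43.1 to 626.6 and 629.6 CPM (3.87 ± 0.11, adjusted p = 0.0197). The largest fold changes upward were in SCAF1 (8.31), FMNL3 (7.98), the noncoding gene AC087190.3 (7.14), TUBB2B (6.94), EPS15 (5.51) and LSM12 (4.67), with edgeR adjusted p values from 0.0316 to 0.0491. In SCAF1, FMNL3, LSM12 and EPS15 between 0.65 and 0.999 of the counts changed transcript between libraries. TUBB2B has a near-identical paralog, and AC087190.3 is annotated as a 3' overlapping noncoding RNA that may hold reads of another gene. These values are uncertain as levels of a gene. LTBP2 had a T24 shift of 0.58, and SET and ASNS, given below, had 0.73 and 0.33. Lower genes were RPL37 (-2.65 ± 0.11), a ribosomal protein gene with pseudogene copies, CDK4 (-2.31 ± 0.10), and AARS (-2.24 ± 0.12), the alanyl-tRNA synthetase. EIF4H (-2.09), ASNS (-2.05), the asparagine synthetase, DUSP1 (-1.90), a MAP kinase phosphatase, WSB2 (-1.88) and SET (-1.41) were lower too, all 8 with edgeR adjusted p values from 0.0316 to 0.0491. Among composition-stable genes 101 rose and 84 fell. The heme oxygenase gene HMOX1 (2.31 ± 0.09, adjusted p = 0.0104), RAB31 (3.32 ± 0.26), the pro-apoptotic BMF (2.87 ± 0.28), BRD3 (2.74), F2RL1 (2.21), FLRT3 (2.09) and the chemokine CXCL8 (1.97 ± 0.19) were among the genes that rose most. GUCY1A2 (4.81) was at 0.07 CPM in the control and 1.95 CPM in each knockdown library. WRN (-2.73), a DNA helicase, ZRANB1 (-2.66), HIGD1A (-2.61), SURF2 (-2.27) and FAM167A (-2.22) fell most besides the genes named above. Leaving out any 1 knockdown library, of T24 or of UMUC3, gave 0 T24 calls by edgeR over all genes (1971 to 2454 at an unadjusted p under 0.05). Among composition-stable genes there were 9 and 7 T24 calls without a T24 library, and 162 without either UMUC3 library. Of the 9 genes of this set called over all genes, 5 and 4 were among the former and all 9 among the latter.

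DNA replication genes were shifted downward in T24 (25 of 31 negative, median -0.38, camera adjusted p = 8.72e-08, fry adjusted p = 0.017, adjusted p = 0.299 with an estimated correlation). No member passed over all genes, 14 fell and 1 rose adjusted over the list alone, and 5 fell among composition-stable genes. The smallest p values were those of the helicase gene MCM2 (-0.92 ± 0.09, adjusted p = 0.0283) and the licensing factor CDC6 (-0.82 ± 0.09, adjusted p = 0.0316). Mesenchymal markers (median 0.77, camera adjusted p = 5.83e-06, 0.299 with an estimated correlation) had 1 call over all genes, FBN1 (1.39 ± 0.09, edgeR adjusted p = 0.0491), and 16 upward and 1 downward adjusted over the list alone. The integrin ITGA5 (1.42 ± 0.09) and N-cadherin CDH2 (0.77 ± 0.08) rose among composition-stable genes. Matrix proteases (median 0.65, camera adjusted p = 1.67e-05, 0.299 with an estimated correlation) had 12 members up and 2 down adjusted over the list alone. The urokinase receptor PLAUR (0.94 ± 0.09) and MMP16 (1.42 ± 0.17) rose among composition-stable genes. TGF-beta response genes (median 0.83, camera adjusted p = 4.52e-05, 0.299 with an estimated correlation) had LTBP2 and the receptor TGFBR2 (1.38 ± 0.07, edgeR adjusted p = 0.0316) among their calls, and 8 upward and 2 downward adjusted over the list alone. Among composition-stable genes this list did not pass (4 of 7 positive, median 0.119, camera adjusted p = 0.175). Inflammatory genes (21 of 27 positive, median 0.59, camera adjusted p = 0.000446, 0.299 with an estimated correlation) had 4 upward and 1 downward in that count. The chemokines CXCL1 (1.40 ± 0.08) and CXCL6 (1.75 ± 0.12) rose and IL11 (-0.92 ± 0.13) fell among composition-stable genes. Integrins (median 0.26, camera adjusted p = 0.000493), immediate early genes (0.28, adjusted p = 0.0268) and histones (0.72, adjusted p = 0.0228) were shifted upward. Cholesterol synthesis (-0.28, adjusted p = 0.00285) and ribosomal genes (-0.13, adjusted p = 0.015) were shifted downward. These 5 lists had adjusted p values of 0.324 to 0.712 with an estimated correlation. Among composition-stable genes immediate early (camera adjusted p = 0.264) and cholesterol genes (0.0547) did not pass. Immediate early genes held members that moved apart, with JUN higher and DUSP1 lower over all genes, and IER3 (1.45 ± 0.10) and FOSL2 (0.51 ± 0.07) higher among composition-stable genes. The ATF4 response list stood at a camera adjusted p of 0.05 downward (median -0.291), and among composition-stable genes at 0.928 upward (median 0.237, 7 of 12 positive). Over all genes it had ASNS and the amino acid transporter SLC7A5 (-1.09 ± 0.07, edgeR adjusted p = 0.0491) lower and 6 up against 11 down adjusted over the list alone. DDIT4 of that list also fell (-0.86), while ID3 (1.26) and the ferritin gene FTH1 (0.72) rose among composition-stable genes. KRT18 (-1.04 ± 0.11), RRM2B (-1.90 ± 0.14) and the heterochromatin protein gene CBX5 (-1.05 ± 0.11) fell among composition-stable genes. Mitochondrially encoded genes moved upward together beside these groups. They held 2.68% of named counts in the T24 control and 3.36 and 3.5% in the knockdown libraries. All 10 passed adjusted over the list alone, and none over all genes (MT-ND5 0.50 ± 0.07, MT-ND1 0.61 ± 0.09; camera adjusted p = 8.72e-08, 0.35 with an estimated correlation).

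In UMUC3, DAG1, NDRG1 and CALR were among the genes with more mRNA in the knockdown libraries, and TRAF1, NFKBIA and CD82 among those with less. Over all genes edgeR called 89 genes higher and 45 lower (3490 at an unadjusted p under 0.05; DESeq2 1715, voom 0). Transcript changes of 0.88 or more of the counts accompanied APC (7.02), FMNL3 (4.81), C22orf46 (4.54), ZDHHC7 (4.44), SEMA5A (-7.93) and PTPRS (-4.12). DAG1, the dystroglycan gene, rose from 11.6 to 271.3 and 280.5 CPM (4.57 ± 0.11, adjusted p = 0.0214) with a shift of 0.17 in UMUC3 and 0.96 in T24. SAMD1, which has a single transcript in the table, rose from 7.8 to 121.9 and 119.5 CPM (3.96 ± 0.17, adjusted p = 0.0237). TUBB2B rose in UMUC3 too (4.52 ± 0.30). HERC2 (-3.86) and PTBP3 (-3.62) fell with shifts of 0.32 and 0.47. TRAF1 (-3.77 ± 0.27), a TNF receptor adaptor, CD82 (-3.45 ± 0.23), a tetraspanin, the splicing factor gene SF3B4 (-3.21 ± 0.18) and the transcription factor gene NFYA (-3.21 ± 0.23) fell over all genes. They had an edgeR adjusted p of 0.00906 each among composition-stable genes. In that set 332 genes rose and 236 fell. Those that rose most were IL6R (3.63 ± 0.23), TCF7L1 (3.40 ± 0.18), AARS (3.33 ± 0.13, from 24.2 to 257.1 and 230.3 CPM), THAP4 (3.25), EPM2AIP1 (3.21), SNX22 (2.98), MRFAP1 (2.83) and NUDCD3 (2.67), with edgeR adjusted p values from 0.00694 to 0.0229. BMF (-2.84 ± 0.47, from 1.97 to 0.14 and 0.39 CPM), WSB2 (-2.76 ± 0.09), the chemokine CCL2 (-2.63 ± 0.26, from 68.0 to 8.7 and 13.2 CPM) and CDK4 (-2.58 ± 0.08) followed among those that fell. Leaving out any 1 knockdown library, of T24 or of UMUC3, gave 0 UMUC3 calls by edgeR over all genes (2843 to 2981 at an unadjusted p under 0.05). Among composition-stable genes there were 298 and 395 calls without a UMUC3 library, and 303 and 290 without a T24 library.

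The unfolded protein and ATF4 response list was shifted upward in UMUC3, with 28 of 30 members positive (median 0.52, camera adjusted p = 2.19e-09, fry adjusted p = 0.0304, adjusted p = 0.389 with an estimated correlation). The chaperone gene CALR (1.253 ± 0.101, edgeR adjusted p = 0.0449) passed over all genes, 15 members rose and 1 fell adjusted over the list alone, and DDIT4 (1.39 ± 0.12, adjusted p = 0.0118) rose among composition-stable genes. Inflammatory and NF-kB genes were shifted downward (18 of 27 negative, median -0.99, camera adjusted p = 8.46e-05, 0.389 with an estimated correlation), with 8 down and 0 up adjusted over the list alone. NFKBIA (-1.52 ± 0.13, edgeR adjusted p = 0.047), the NF-kB inhibitor, fell over all genes, and CXCL1 (-0.94 ± 0.07) and CCL2 fell among composition-stable genes. Cholesterol synthesis genes were shifted downward (19 of 24 negative, median -0.48, camera adjusted p = 9.03e-05, 0.389 with an estimated correlation), with 13 down and 1 up adjusted over the list alone. SQLE (-0.71 ± 0.08) fell among composition-stable genes. Hypoxia and glycolysis genes (median 0.23, camera adjusted p = 0.00304, 0.429 with an estimated correlation) had 4 members up adjusted over the list alone. NDRG1 rose from 76.3 to 846.7 and 808.9 CPM (3.44 ± 0.10, edgeR adjusted p = 0.0235) and the mitophagy receptor BNIP3L rose by 1.40 ± 0.13 (adjusted p = 0.047), while ADM (0.93 ± 0.11) rose among composition-stable genes. Mitosis genes (median 0.16), DNA replication genes (0.16) and immediate early genes (0.30) each had a camera adjusted p of 0.0153 upward and of 0.471 to 0.485 with an estimated correlation. Among composition-stable genes immediate early genes did not pass (camera adjusted p = 0.097). Ribosomal genes were shifted downward (-0.11, camera adjusted p = 0.0213, 0.62 with an estimated correlation). Adjusted over the list alone, 4 mitosis genes and 4 replication genes rose, and 6 immediate early genes rose and 2 fell. Among composition-stable genes GINS2 (0.94 ± 0.15), CHAF1A (0.61 ± 0.10), CCNB2 (0.66 ± 0.08), CENPF (0.89 ± 0.13), SPRY2 (0.67), CDH2 (0.46) and JUND (1.15 ± 0.13) rose, and PLK1 (-0.36 ± 0.07) fell. Mesenchymal (camera adjusted p = 0.163) and epithelial markers (0.172) did not pass as lists. The collagen gene COL5A1 (2.41 ± 0.19), the WNT antagonist DKK1 (1.68) and the protease gene ADAM19 (1.84 ± 0.11) rose over all genes. The tight junction gene CLDN1 (-2.47 ± 0.18), PLAU (-1.64 ± 0.08), AGO2 (-1.39 ± 0.10), which encodes the Argonaute protein of RNA interference, and CDKN1A (-2.33 ± 0.15) fell over all genes, and these 7 genes had edgeR adjusted p values from 0.0284 to 0.047. The EMT regulator SNAI2 (2.02 ± 0.32) rose and RRM2B (-1.22 ± 0.14) fell among composition-stable genes. Mitochondrially encoded genes held 4.62% of named counts in the UMUC3 control and 4.26 and 4.62% in the knockdown libraries (camera adjusted p = 0.63).

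**Figure D2:**
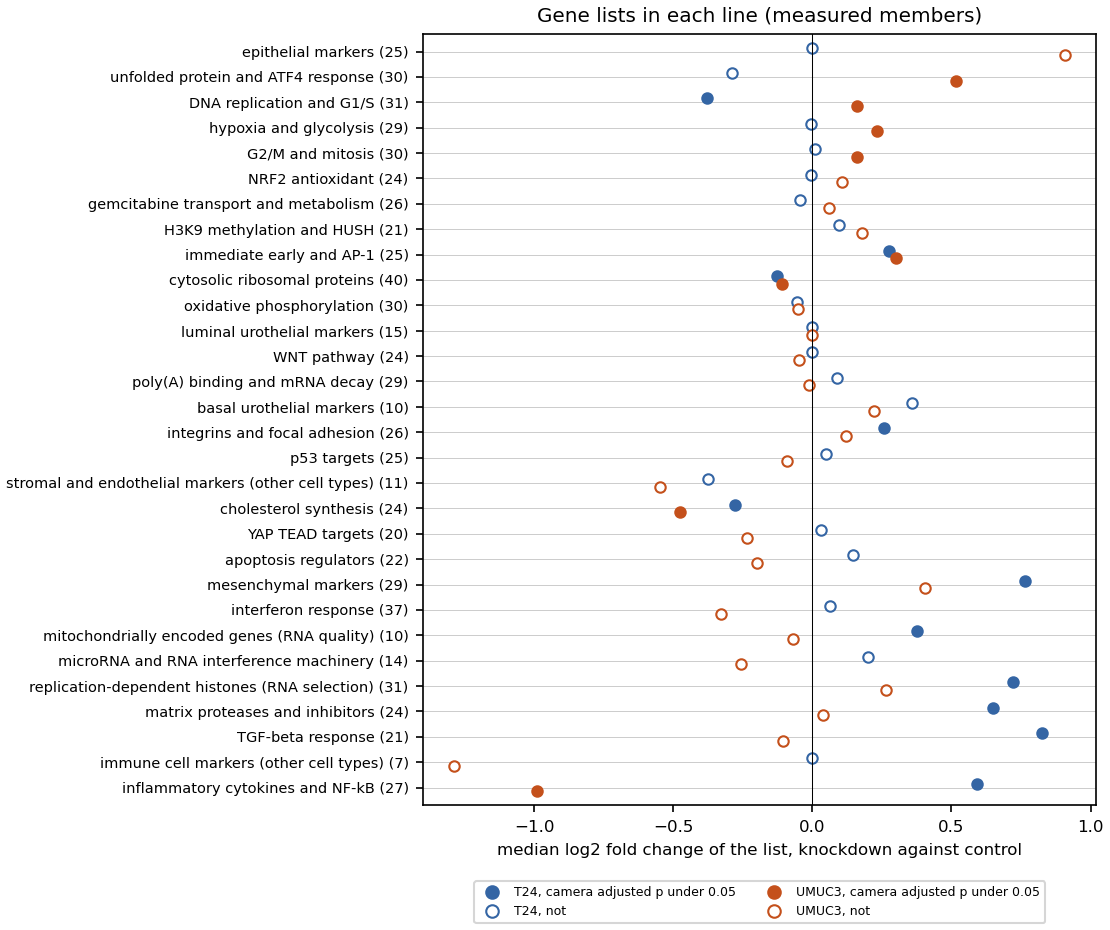
Median log2 fold change of each gene list over all measured members (number in brackets), knockdown against control, in T24 and UMUC3. Filled circles have a camera adjusted p under 0.05 with the preset correlation. The inflammatory list stands at 0.59 in T24 and -0.99 in UMUC3, and the DNA replication list at -0.38 and 0.16.

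The difference between the lines was tested as an interaction, positive where the change was higher in UMUC3. AARS (ENSG00000090861, chromosome 16, 70252295 to 70289543) fell in T24 and rose in UMUC3, and its changes differed by 5.57 ± 0.19 on the log2 scale (edgeR adjusted p = 0.0233). JUN, which rose in T24, stood at 0.48 ± 0.07 in UMUC3 (edgeR adjusted p = 0.0873; interaction -4.61 ± 0.10, adjusted p = 0.0185), and LTBP2, which rose in T24, stood at -1.17 ± 0.12 there (adjusted p = 0.0553; interaction -5.03 ± 0.15, adjusted p = 0.021). The changes of MRFAP1, TAF7, DAG1 and NDRG1 were higher in UMUC3 than in T24, by 3.14, 3.42, 4.47 and 2.32 (adjusted p = 0.0487, 0.0487, 0.021 and 0.0487). Shifts were 0.63 for TAF7 and 0.46 for NDRG1 in UMUC3, and 0.96 for DAG1 in T24. SEMA5A (-8.61) and SCAF1 (-7.97) also differed, with the transcript changes given above. Over all genes edgeR called 8 differences upward and 4 downward (2789 at an unadjusted p under 0.05; DESeq2 1120, voom 0), and among composition-stable genes 87 and 67. In the latter set BMF rose in T24 and fell in UMUC3 (interaction -5.71 ± 0.54, edgeR adjusted p = 0.0283), and so did CXCL1 (-2.33 ± 0.11, adjusted p = 0.0206) and CXCL8 (-3.02 ± 0.25, adjusted p = 0.0283). BMF was low in UMUC3, at 1.97 CPM in the control and 0.14 and 0.39 CPM after knockdown. CXCL8 was at 39.3 CPM in the UMUC3 control and 16.7 and 21.1 CPM after knockdown. THAP4, EPM2AIP1, SNX22 and TCF7L1 lay 2.89 to 3.45 higher in UMUC3, and GUCY1A2, CCL2, TRAF1, SF3B4 and CD82 lay lower, with interactions of -4.87 to -3.04. SETDB1 (-0.04 ± 0.56), PTK2 (0.66 ± 0.82) and PABPC1 (-0.48 ± 0.12, edgeR adjusted p = 0.26) did not differ past the threshold. Leaving out any knockdown library gave 0 calls by edgeR over all genes, and 3, 9, 88 and 127 among composition-stable genes, with the 2 lowest counts on leaving out a T24 library.

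By gene list, replication genes differed upward (27 of 31 positive, median 0.54, camera adjusted p = 9.34e-09, 0.271 with an estimated correlation), and 15 members passed upward and 0 downward adjusted over the list alone. PCNA (0.76 ± 0.09) and CHAF1B (1.42 ± 0.17) passed among composition-stable genes. The ATF4 and unfolded protein list differed upward (median 0.82, camera adjusted p = 2.73e-09, 0.271 with an estimated correlation; 14 up and 1 down adjusted over the list alone), with SLC7A5 (1.505 ± 0.10) and DDIT4 (2.25 ± 0.17) among its composition-stable members. The inflammatory list differed downward (21 of 27 negative, median -1.62, camera adjusted p = 1.19e-06, 0.271 with an estimated correlation; 8 down and 1 up adjusted over the list alone). TGF-beta (median -0.69, camera adjusted p = 0.000121), protease (-1.08, adjusted p = 0.00244), NRF2 (-0.32, adjusted p = 0.00423), and microRNA machinery genes (-0.49, adjusted p = 0.0253) differed downward. So did interferon (-0.33, adjusted p = 0.026), cholesterol (-0.45, adjusted p = 0.0163) and integrin genes (-0.09, adjusted p = 0.0399). Mitosis (0.20, adjusted p = 0.0118) and hypoxia genes (0.15, adjusted p = 0.0208) differed upward. These 9 lists each had an adjusted p of 0.309 to 0.418 with an estimated correlation. Among composition-stable genes TGF-beta (median -0.314, camera adjusted p = 0.176), interferon (-0.122, adjusted p = 0.528) and integrin genes (-0.037, adjusted p = 0.775) did not pass. The mean of the NRF2 list was 0.08, above 0 where its median and test were below. TGFBR2 (-1.49 ± 0.09), PLAUR (-1.30 ± 0.12), HMOX1 (-1.61 ± 0.12), ITGA5 (-1.27 ± 0.12) and AGO2 (-1.12 ± 0.14) passed downward and BNIP3L (1.52 ± 0.15) upward among composition-stable genes. Mitochondrially encoded genes differed downward with these groups (10 of 10 negative, median -0.45, camera adjusted p = 2.19e-06, 0.309 with an estimated correlation).

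The fold changes of the lines were nearly uncorrelated across genes. Spearman's rho was 0.043 and Pearson's r 0.054 over 20721 genes, and 0.122 and 0.107 over the composition-stable genes, where genes are not independent replicates. The lines share no library, so no control links these values. Both lines' calls come from 1 fit with 1 dispersion per gene, so a gene of low spread is more readily called in both, and counts expected of independent lists are no baseline for unrelated changes. Over all genes 5 genes rose in both lines (0.08 expected of independent lists) and 3 fell in both (0.02 expected), while 0 rose in T24 and fell in UMUC3 and 1 fell in T24 and rose in UMUC3 (0.04 expected each). Among composition-stable genes 30 rose in both against 7.3 expected, and 37 fell in both against 4.32 expected. Of the genes that rose in T24 in this set, 9 fell in UMUC3 (5.19 expected), and of those that fell in T24, 9 rose in UMUC3 (6.07 expected).

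**Figure D3:**
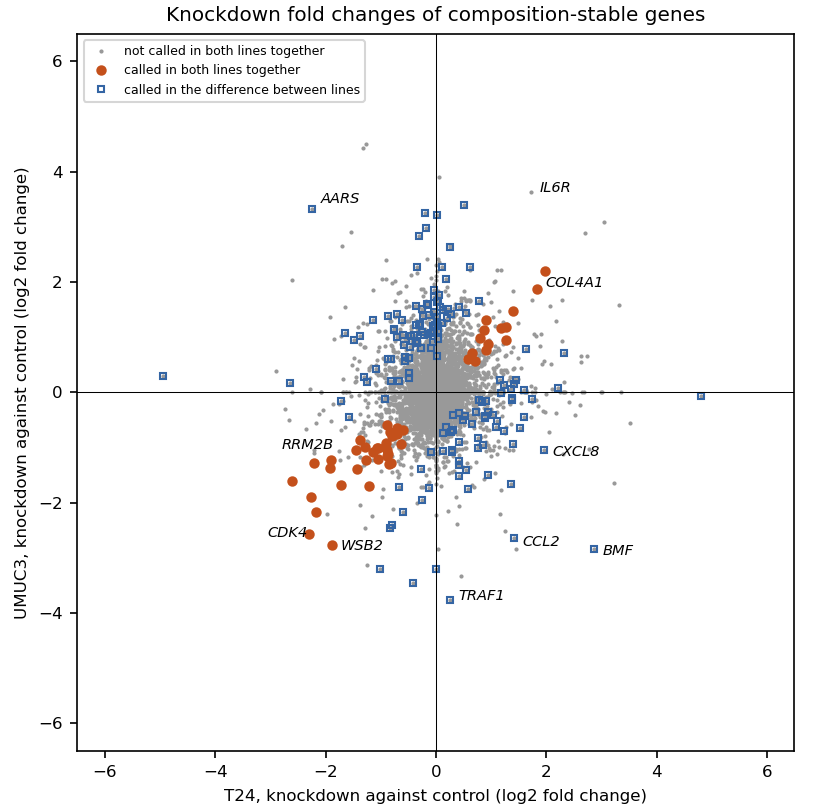
Log2 fold changes of knockdown against control in T24 (horizontal axis) and UMUC3 (vertical axis) for the 4593 composition-stable genes, of which 1 lies outside the axes. Filled circles are the 47 genes called in both lines together and open squares the 154 genes whose change differed between lines, AARS and BMF among them.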

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

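The interaction test of single genes was planned, whereas the composition-stable set, the gene-list tests on the difference between lines and the share of unnamed transcripts were chosen after the results were seen.

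These results drew attention because the change after knockdown differed between T24 and UMUC3 by the edgeR interaction test, given here as the UMUC3 change minus the T24 change on the log2 scale. Over all genes the difference was 5.57 for AARS, 4.47 for DAG1, 3.42 for TAF7, 3.14 for MRFAP1 and 2.32 for NDRG1. It was -8.61 for SEMA5A, -7.97 for SCAF1, -5.03 for LTBP2 and -4.61 for JUN. Among composition-stable genes it was 3.45 for THAP4, 3.20 for EPM2AIP1, 3.15 for SNX22 and 2.89 for TCF7L1, and -5.71 for BMF, -4.87 for GUCY1A2, -4.06 for CCL2, -4.02 for TRAF1, -3.21 for SF3B4 and -3.04 for CD82. Each line has a single control library, so a control that was unlike other controls of its line would shift every difference of this kind, and the design offers no second control to measure that.

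The JUN difference follows the T24 control, where JUN stood at 7.9 CPM against 265.0 CPM or more in each other library. DAG1, at 11.6 CPM, was likewise low in the UMUC3 control alone among the 6 libraries. So were TAF7 (12.1 CPM against 118.1 or more), MRFAP1 (33.7 against 230.5 or more), THAP4 (7.1 against 62.6 or more) and EPM2AIP1 (4.5 against 33.2 or more). SCAF1 was low in the T24 control alone (0.56 CPM against 156.3 or more). TRAF1 (47.7 CPM) and CCL2 (68.0 CPM) were high in the UMUC3 control alone. In NDRG1, LTBP2, SNX22, SF3B4 and CD82 the paired knockdown libraries of 1 line stood apart instead.

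By gene list, camera with the preset correlation separated the lines for the ATF4 and unfolded protein response (median difference 0.82), DNA replication (0.54), mitosis (0.20) and hypoxia genes (0.15), which lay higher in UMUC3. Inflammatory (-1.62), protease (-1.08), TGF-beta (-0.69), microRNA machinery (-0.49), mitochondrially encoded (-0.45), cholesterol (-0.45), interferon (-0.33), NRF2 (-0.32) and integrin genes (-0.09) lay lower there. With an estimated correlation 0 of these lists passed camera, and 5 lists passed fry.

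Transcripts with neither a gene nor a position entered no comparison. They held 15.92% of counts (mean of 2 knockdown libraries, SD 0.25) in T24 against 14.86% in its control, and 15.63% (SD 0.29) in UMUC3 against 15.42% in its control. No biological explanation was tested for any of these differences.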

How the results depend on the processing

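Tests on composition-stable genes, their limits of 0.1 and 0.5, and the gene-list tests on the difference between lines were chosen after seeing the data, and the other alternatives were planned. Counts of called genes are given in the order both lines together, T24, UMUC3 and difference, where the main edgeR counts were 3, 28, 134 and 12.

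DESeq2 called 981, 980, 1715 and 1120 genes and limma voom 2, 0, 0 and 0, with 2400, 2598, 3490 and 2789 genes at an unadjusted p under 0.05 in edgeR. Without a count filter edgeR called 8, 43, 224 and 35. The legacy fit called 2, 2, 13 and 5, the non-robust fit 3, 19, 23 and 4, and the test against a fold change of 1.5 called 3, 11, 21 and 5. RLE size factors gave 3, 28, 135 and 5, library sizes alone 3, 26, 134 and 12, and the filter of 50 counts 3, 20, 121 and 4. With the siRNA number as a replicate block, from titles or from column names, 0 genes passed edgeR in each comparison over all genes. The block was not run on composition-stable genes alone. Libraries of 1 line alone gave 0 calls in T24 and 0 in UMUC3 by edgeR, and the mean of the per-line contrasts gave 185 for both lines together. Apart from features of the design, the cause of these shifts was not tested. Fewer samples leave fewer residual degrees of freedom. The main fit of both lines together counts a difference between the lines as spread, while the mean of the per-line contrasts does not. For JUN the SE was 1.13 in that main fit and 0.09 in T24. Fits without a control library, given next, also count no such difference as spread.

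Leaving out each library in turn gave 0 to 134 calls for both lines together by edgeR. In T24, UMUC3 and the difference only knockdown libraries were left out, which gave 0. The highest count came without the T24 control, and 25 genes passed without the UMUC3 control. Among composition-stable genes 47, 185, 568 and 154 genes passed. The limit of 0.1 gave 40, 210, 481 and 169, and the limit of 0.5 gave 17, 65, 326 and 16. In that set, leaving out each library gave 2 to 570 for both lines together, and leaving out each knockdown library gave 7 to 162 in T24, 290 to 395 in UMUC3 and 3 to 127 for the difference. Of the calls over all genes that were also composition-stable, 2 of 2, 9 of 9, 67 of 67 and 3 of 3 passed there too. The same counts were refitted there with a lower common dispersion, so this is no separate evidence for those calls.

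Gene lists passing camera numbered 11, 11, 8 and 13. With an estimated correlation the counts were 0 in each comparison, with fry 0, 9, 5 and 5, with the filter of 50 counts 11, 12, 8 and 13, and among composition-stable genes 6, 6, 7 and 9. The correlation between lines was 0.043, against 0.063 with the filter of 50 counts, 0.122 among composition-stable genes and 0.027 to 0.05 on leaving out a knockdown library. The siRNA number check was -0.001, against -0.004 with the filter of 50 counts and -0.002 among composition-stable genes, all too near 0 to settle the numbering.

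Reversals of sign were seen in genes that had not passed. PABPC1 in both lines together went from -0.08 to 0.16 without the UMUC3 control and to -0.31 without the T24 control. SETDB1 went from 0.04 to -0.15 without T24 knockdown replicate 1, to 0.17 without replicate 2 and to -0.06 without UMUC3 knockdown replicate 2. In T24 it went from 0.06 to -0.36 without replicate 1 and to 0.38 without replicate 2, and in UMUC3 from 0.02 to -0.22 without replicate 2 and to 0.22 without replicate 1. In the difference SETDB1 went from -0.04 to 0 with library sizes only, to 0.38 without T24 knockdown replicate 1, to -0.36 without replicate 2 and to 0.16 without UMUC3 knockdown replicate 1, and PTK2 went from 0.66 to -0.12 without UMUC3 knockdown replicate 2 and to 1.16 without replicate 1. Scaling by DESeq2, RLE or library sizes alone moved the median of all genes by less than 0.1.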

Other observations

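Of the tests here, those comparing 3' UTR with coding sequence were written before their result was seen, and the others were chosen after the results were seen.

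With each library of a line taken in turn as its control, 1 of the 9 choices called as many genes as the real one, which is the real choice itself. It called 3 genes over all genes, and the highest other choice called 2. Among composition-stable genes it called 47, and the highest other choice called 2. The 9 choices are too few for a share under 0.05.

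Fewer genes passed over all genes than among composition-stable genes. Lower expression may account for the spread of genes with 1 transcript, whose median absolute log2 difference between paired knockdown libraries was 1.87 and 1.84 times that of composition-stable genes in T24 and UMUC3, and 1.04 ± 0.062 and 1.08 ± 0.067 times (± bootstrap SE) at matched mean CPM. For genes with a shift of 0.2 or more it is argued against as the whole cause: with genes split by their shift in the other line, the ratio at matched mean CPM was 1.39 ± 0.038 in T24 and 1.33 ± 0.036 in UMUC3. For these, reads that the authors' quantification gave to different transcripts in different libraries are a candidate explanation, and real changes in transcript use stay open.

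In a search of 16384 possible 7-base sequences, genes with TGACAGA in the 3' UTR lay lowest in each of the 4 knockdown libraries against its line's control (805 composition-stable genes, z -4.91 and -5.64 in T24, -4.2 and -4.38 in UMUC3, where libraries of a line share a control). Chance is argued against in both lines together (z -6.23, permutation p = 0.001, the smallest that 1000 shuffles can give) and in T24 (p = 0.003), while UMUC3 alone had p = 0.103 in this set and 0.002 over all genes, and sequences of the same bases that do not overlap it by 6 bases reached no lower than -3. Of 32 searched genes called lower in both lines together 16 carry it, NAA50, RASSF3 and RRM2B among them, which restates the pattern. It also lies at 3 places in exons of PTK2. One of these is in 22 transcripts and starts 4 or 5 bases into an exon, and the others are in 1 transcript each. Chance alone could give such places, and they were not tested. A seed of 1 of the 2 siRNAs of a line as the source is argued against, since the mean shifts in its paired libraries differed by 0.016 ± 0.014 in T24 and -0.002 ± 0.015 in UMUC3, against mean shifts of -0.104 and -0.101. An RNA common to the knockdown cells that binds 3' UTRs may be the source. The prediction was that genes with 3' UTR sites only lie lower than genes with coding sites only in each line. They differed by -0.044 ± 0.028 in both lines together, by -0.096 ± 0.034 in T24 and by 0.002 ± 0.038 in UMUC3. The prediction was thus met in T24 and not in UMUC3, where genes with coding sites lay as low (-0.075 against -0.073). The split between the lines leaves this source open, and the siRNA sequences are not given in the sources used here.

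Genes with TCGGAGA in the 3' UTR lay higher after knockdown in UMUC3 (97 genes, mean log2 0.44, z 7.62, permutation p = 0.001, the smallest that 1000 shuffles can give). A control siRNA acting alike in both lines is argued against by z 0.51 in T24. Genes with sites only in the 3' UTR exceeded those with coding sites only by 0.326 ± 0.097 in UMUC3, so an RNA in the UMUC3 control cells that binds 3' UTRs is a candidate source of part of the UMUC3 fold changes. Genes with coding sites only were higher too, by 0.172 ± 0.040 against genes with no site, and over all genes the values were 0.339 for the 3' UTR and 0.206 for coding sites. The sequence was picked by its 3' UTR shift, which enlarges that difference, and the sequence of the control siRNA is not given in the sources used here. Over all genes in UMUC3, AGGAGAA (3253 genes, z 6.02) and GGAGAAA (2865 genes, z 5.12) came next after TCGGAGA (z 6.74). The largest absolute z of a shuffle had a median of 4.06. Higher values were thus not confined to genes with TCGGAGA, and the other sequences were not tested further.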
